A study of Mus musculus with 6 samples.

How the data were processed

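Bulk RNA sequencing was analysed from 6 samples of mouse cells, 3 treated with BW723C86 and 3 with its vehicle DMSO. BW723C86 is an agonist of the serotonin receptor 5-HT2B. Per the series' title, the sequenced cells were bone marrow-derived macrophages (BMDMs), which are macrophages grown from mouse bone marrow precursors. They sat in the upper chamber of a Transwell, whose porous membrane lets soluble factors pass, above HT22 cells, a mouse hippocampal neuronal line, that had been deprived of oxygen and glucose (OGD) for 2 h. The design text of the series allows either BV2 microglia or BMDMs in the upper chamber, and the sample labels name BMDMs together with HT22, so the cells are called macrophages here on the authority of the title. The dose, the length of treatment and the number of separate cultures or animals are not given in the sources used here.

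Per the labels' protocols, total RNA of checked integrity was selected for poly(A), fragmented and copied into strand-marked cDNA by incorporation of dUTP, and the libraries were sequenced as paired ends on an Illumina instrument. Per the submitters' processing notes, fastp, HISAT2, StringTie and edgeR were used, and the builds GRCm39 and GRCh38 are named. Those notes, as used here, give no version, role or order, and whether counting used strand is not given in the sources used here. The deposited values are estimated counts per gene, all whole numbers, so that rounding changed none of them. Their low values pile up at multiples of 4: the value 4 occurs 4613 times, against 2904 times for 3 and 2552 times for 5. The number of counts that a single sequenced fragment is worth is therefore uncertain, and counts divided by 4 were tried as an alternative.

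The table held 28822 gene identifiers, of which 4300 had no count in any sample, and no row lacked a gene. Symbols for 27005 identifiers came from GENCODE release M21, which describes a different build from those named, so it was used for names, gene type, GC content and transcript length and no coordinates are given. Total counts per library ran from 58841307 to 75931615. A count of 3, taken as the detection floor, corresponds to 0.0395 to 0.051 CPM (counts scaled to a common library total, as edgeR gives them), and covers counting error only. If a fragment is worth 4 counts, a count of 3 lies below a single fragment, so that this floor is uncertain. Members of multigene families (Ly6, H2, the Rnase2 and Ear ribonucleases, Ccl6 and Ccl9, kallikreins, histones, ribosomal proteins, Gapdh) are uncertain where near-identical copies may share reads, and so are overlapping and antisense genes.

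Samples were grouped by the treatment label. Before replicates were averaged, their counts were compared over genes with a summed count of at least 40. Taken over all these genes together, every pair within a group differed by more than sampling noise, even with counts divided by 4 (chi-square per degree of freedom 2.46 to 8.88). All 6 were therefore kept as separate samples. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

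The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust fit, TMM scaling, the tool's default filter on expression by group), two-sided, with Benjamini-Hochberg adjustment over 15567 tested genes and a threshold of 0.05. Standard errors (SE) are of the log2 fold change, BW723C86 over DMSO. A total of 43 gene lists, written from textbook knowledge before the data were examined, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, adjusted over the 43 lists. Beside it, camera with an estimated correlation and the rotation test fry were run. In the text, adjusted p of a gene is edgeR's and adjusted p of a list is camera's. Members of a list were counted past the test over all genes tested and also adjusted over the list alone. Summed CPM of marker lists were compared by a two-sided exact permutation test, for which 3 against 3 samples cannot give a p below 0.1.

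The genes named were set by a rule fixed before the data were examined: the 10 largest changes in each direction among named, non-pseudogene genes past the threshold with a mean of at least 5 CPM and no overlap between groups, the 5 smallest p in each direction under the same limits, up to 4 members of smallest p of each list past the threshold, and a fixed panel of receptors, cytokines and macrophage genes. Slc6a4, Mmp8, Kit, Lyz2, Cd80, H2-Oa, H2-DMb2 and Il1rn in the report and other genes named in the closing section were chosen after their values were seen. A few genes that the rule named are not reported here. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters, a non-robust fit, the replicate number as a block, each library left out in turn, a test against a fold change of 1.2, and, for lists and marker sums, other set tests and medians. Added after seeing the data were counts divided by 4, removal of each library's trend with GC content and transcript length, omission of mitochondrially encoded genes, and gene families formed by shared symbol letters.

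The tests were tested on simulated data before use. With 200 of the simulated genes changed in a BW723C86 against DMSO comparison of 15346 genes, the fit recovered 52% of 50 genes at a fold of 1.25, 66% at 1.5, 84% at 2 and 98% at 4. Of its 160 calls, 10 were false, and camera found the shifted list and called 0 of 20 unshifted lists. Simulated genes were drawn independently and most were unchanged, whereas in the data 42% of tested genes changed. Correlations estimated within the lists of the data reached 0.83 (mitochondrially encoded transcripts). The simulation therefore does not show how often camera calls lists of correlated genes.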

Results

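The data were transcriptomes of mouse bone marrow-derived macrophages cultured in the upper chamber of a Transwell above HT22 neuronal cells that had been exposed to 2 h of oxygen-glucose deprivation, an in vitro model of ischaemia. The co-cultures received the 5-HT2B agonist BW723C86 (3 samples) or DMSO (3 samples), and the comparison asked how the agonist changed gene expression in the macrophages. Total counts were 75931615, 58841307 and 75687683 in DMSO replicates 1 to 3 and 59971346, 72562020 and 60647747 in BW723C86 replicates 1 to 3, with 19034 to 20002 genes detected per library. The leading principal component held 56.9% of the variance and separated the groups. By the chi-square of their counts, BW723C86 replicate 2 lay farthest from its group: its counts differed from those of replicates 1 and 3 with a chi-square per degree of freedom of 35.5 and 24.35, against 11.07 between replicates 1 and 3 and 9.83 to 10.43 among DMSO libraries. Over genes with fewer than 400 counts in a pair of libraries, the squared difference relative to counting noise was similar for the 3 BW723C86 pairs (medians of 4.95, 4.49 and 4.44 times that expected). If a fragment is worth 4 counts, these medians lie near counting noise. On the second principal component replicate 2 (-11.6) lay between replicates 1 (42.5) and 3 (-31.4).

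With BW723C86, 17 of 22 genes for pro-inflammatory mediators, 11 of 14 monocyte markers and all 13 neutrophil markers fell. By contrast, 8 of 14 genes of MHC class II antigen presentation, 30 of 35 lysosome and autophagy genes and 20 of 34 phagocytosis genes rose. So did 17 of 24 cholesterol synthesis genes and 21 of 26 NRF2 targets. These 8 lists passed as sets with a preset correlation, and none did with an estimated correlation (adjusted p = 0.057 to 0.33). Serpinb2 (ENSMUSG00000062345), which encodes the plasminogen activator inhibitor PAI-2, fell from 360 ± 9.16 to 1.96 ± 0.182 CPM (SD, n = 3 per group). Thbs1 (ENSMUSG00000040152), encoding the secreted matrix glycoprotein thrombospondin-1, fell from 2220 ± 20.4 to 61.5 ± 2.76 CPM. The chemokine gene Ccl17 (ENSMUSG00000031780), whose product attracts CCR4-bearing T cells, rose from 18.8 ± 1.67 to 286 ± 25.2 CPM, and H2-Aa (ENSMUSG00000036594), an MHC class II chain, rose from 428 ± 5.93 to 2300 ± 87.1 CPM. In all, 6534 of 15567 tested genes changed (42%), 3319 higher and 3215 lower with BW723C86.

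Most of these changes were small. The median absolute log2 fold change of the changed genes was 0.45, and 686 genes were higher and 630 lower by at least 2-fold, 215 and 228 by at least 4-fold. Groups did not overlap for 8149 genes (52.3% of those tested), against 10% by chance. Tested against a fold change of 1.2 in place of no change, 3208 genes passed. Requiring at least 5 CPM in 3 libraries left 289 genes higher and 294 lower by at least 2-fold.

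The receptor that the agonist targets was itself measured at low level. Htr2b (ENSMUSG00000026228), which encodes 5-HT2B, had counts of 9, 5 and 13 in the DMSO libraries and 124, 162 and 172 in the BW723C86 libraries, a rise from 0.122 ± 0.0424 to 2.44 ± 0.405 CPM (log2 fold change 4.28, SE 0.33, adjusted p = 3.2e-07). If a fragment is worth several counts, its DMSO counts rest on very few fragments, so that the size of the fold is uncertain. Htr7, encoding the Gs-coupled receptor 5-HT7, fell from 1.11 ± 0.185 to 0.211 ± 0.0766 CPM (log2 fold change -2.37, SE 0.39, adjusted p = 0.00032). Htr2a, encoding 5-HT2A, stood at 2.36 ± 0.0938 and 2.65 ± 0.63 CPM and did not pass the test (log2 fold change 0.16, SE 0.2, adjusted p = 0.56). Slc6a4, the serotonin transporter gene, rose from 25.4 ± 1.78 to 77 ± 2.94 CPM. Of 24 genes on the serotonin list, 16 were in the table and 8 were expressed enough to be tested. Of these 8, 5 rose and 2 fell, with the same counts adjusted over the list alone, and the list did not pass as a set (adjusted p = 0.071, and 0.26 with an estimated correlation). It passed with the replicate number as a block (adjusted p = 0.049) and without DMSO replicate 3 (0.047).

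Among the largest increases were Rnase2a, an eosinophil-associated ribonuclease gene (log2 fold change 4.32, SE 0.14, adjusted p = 1.6e-10), Mamdc2 (4.13, SE 0.09, adjusted p = 1.6e-12) and Gfra2, encoding a co-receptor for neurturin (3.93, SE 0.13, adjusted p = 8.4e-11). Ccl17 followed at 3.93 (SE 0.08, adjusted p = 1.5e-12). The VEGF receptor gene Flt1 and the long-chain fatty acid receptor gene Ffar4 each rose by 3.57 on the log2 scale (SE 0.15 and 0.13), to 9.39 ± 0.683 and 14.9 ± 1.68 CPM. H2-M2, a non-classical MHC class I gene, rose by 3.49. Dcstamp, required for fusion of osteoclasts and macrophages, rose by 3.22, from 10.6 ± 0.833 to 98.3 ± 0.746 CPM. The semaphorin gene Sema6d rose by 3.14 and St3gal5, encoding the synthase of ganglioside GM3, by 3.06. Plet1 was among the genes with the smallest p at a log2 fold change of 2.34 (162 ± 2.64 to 821 ± 6.08 CPM), as was Itgax, encoding the integrin CD11c, at 2.32 (471 ± 6.7 to 2360 ± 79 CPM).

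Larger folds were seen among the decreases. Serpinb2 had a log2 fold change of -7.51 (SE 0.07, adjusted p = 1.1e-15), Cxcl3, a neutrophil-attracting chemokine gene, one of -6.59 (SE 0.08, adjusted p = 1.4e-14), and the homeobox gene Pitx1 one of -5.88 (SE 0.19, adjusted p = 6.4e-11). Thbs1 was at -5.18 (SE 0.05, adjusted p = 2.4e-15). Ly6c1, of the Ly6 surface protein family, was at -4.97 (SE 0.55, adjusted p = 0.00084), with counts of 43, 12 and 8 in the BW723C86 libraries, and at -6.13 without BW723C86 replicate 1. C5ar1, encoding the receptor for the complement fragment C5a, fell from 88.1 ± 2.24 to 3.22 ± 0.428 CPM, and Fpr1, encoding a receptor for formylated bacterial peptides, from 72.8 ± 2.22 to 4.59 ± 1.04 CPM. The secreted glycoprotein gene Lrg1 fell from 19.4 ± 1.69 to 0.846 ± 0.265 CPM and Ly6a, which encodes Sca-1, from 223 ± 6.46 to 15.6 ± 0.168 CPM. The fibronectin gene Fn1 fell from 2170 ± 15 to 243 ± 4.96 CPM.

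**Figure D1:**
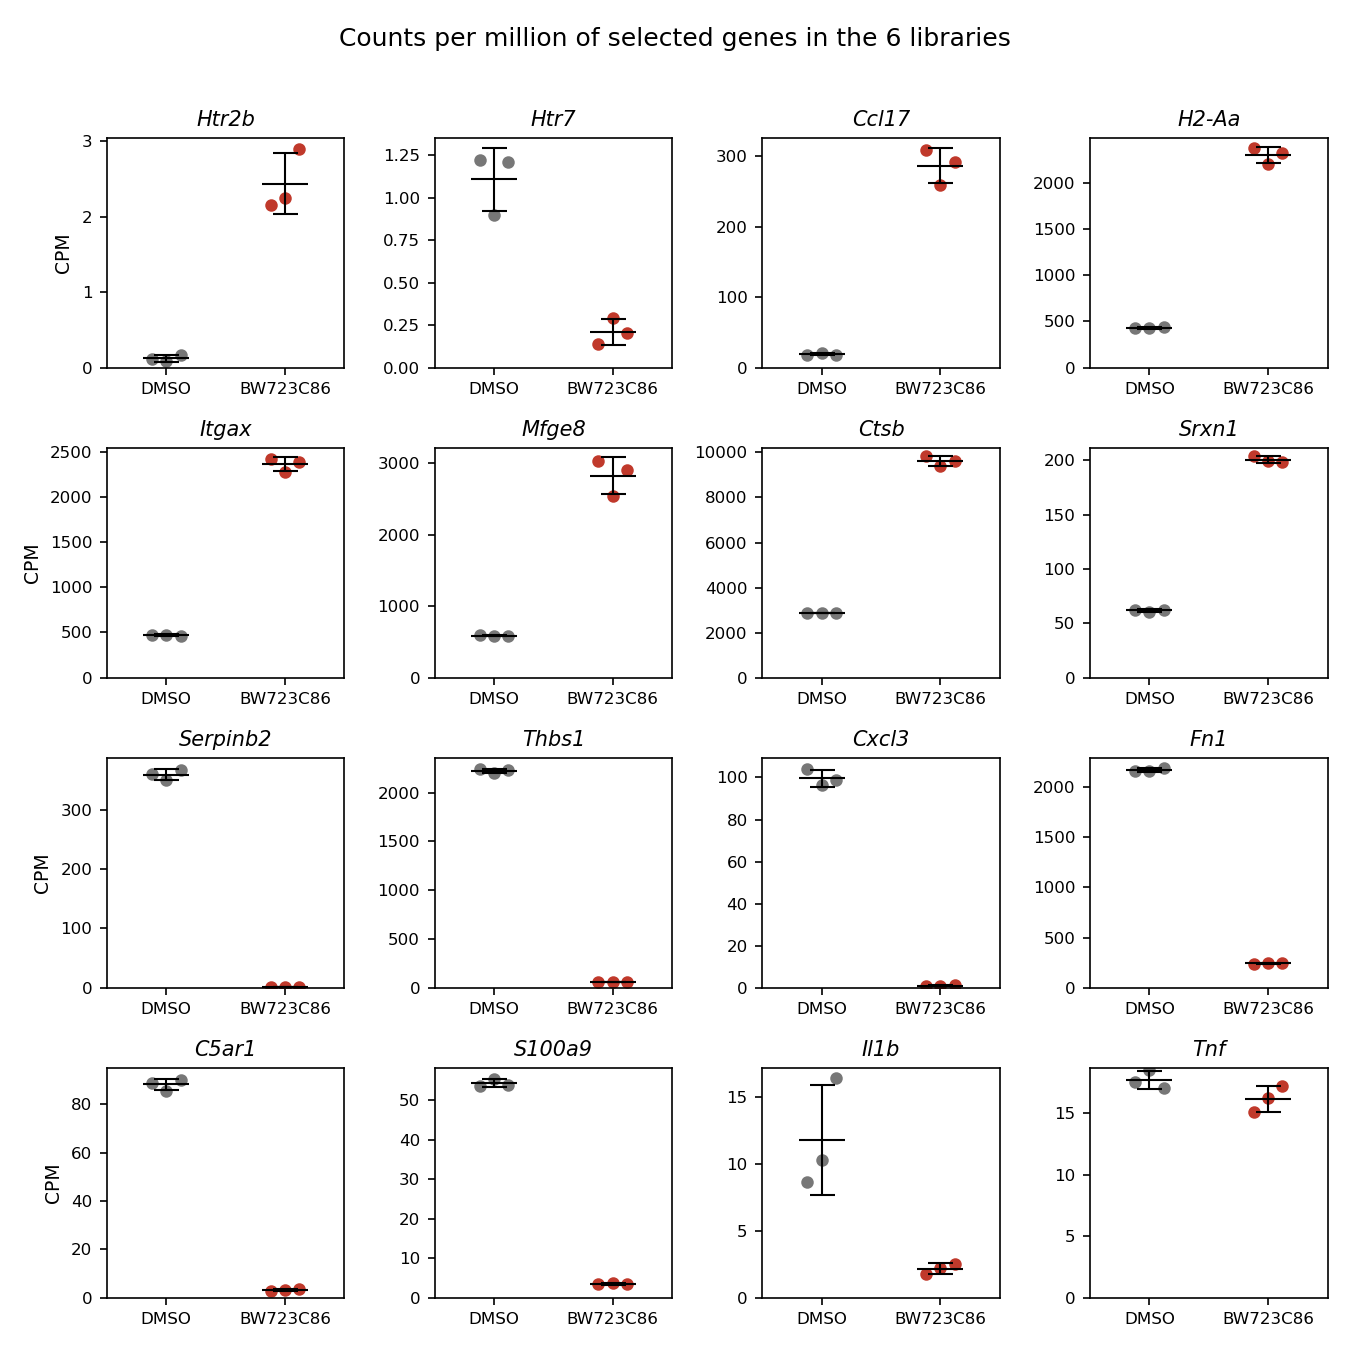
CPM (vertical axis, from 0) of 16 genes in each of the 3 DMSO (grey) and 3 BW723C86 (red) libraries, with the mean and SD as bars. The groups do not overlap for 15 of the genes, and for Tnf, which did not pass the test, BW723C86 replicate 3 lies within the range of the DMSO libraries.

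As sets, 21 of the 43 lists passed the threshold with the preset correlation, 12 higher and 9 lower with BW723C86. With an estimated correlation camera passed 0 of the 43 (12 at an unadjusted p under 0.05), so each list below is given with that p as well and described by the counts of its members. Those counts are no set test, since members may move together. Of all tested genes 42% changed, and 5675 of the 10224 with at least 5 CPM in 3 libraries. The share of changed members was near these in the NF-kB, nuclear oxidative phosphorylation, interferon, TGF-beta and neuronal lists, although these members mostly went the same way. The directional fry test, which asks whether members move on balance in a single direction without reference to other genes, passed for 40 lists.

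Genes for pro-inflammatory cytokines and mediators were mostly lower. Of 22 tested, 17 fell, 1 rose and 4 did not pass, with 17 lower and 1 higher adjusted over the list alone (median log2 fold change -1.19, adjusted p = 4e-07, and 0.057 with an estimated correlation). Lcn2, encoding the siderophore-binding lipocalin-2 and also on the neutrophil list, fell from 52.2 ± 2.45 to 5.8 ± 0.779 CPM. The Toll-like receptor gene Tlr2 fell from 448 ± 6.23 to 173 ± 5.69 CPM. Acod1, encoding the enzyme that makes itaconate, fell from 22.5 ± 1.15 to 6.77 ± 0.85 CPM. Tnfsf9, a gene of the TNF ligand family, fell from 20.6 ± 0.425 to 6.23 ± 0.416 CPM. Il1b, encoding interleukin-1 beta, fell from 11.8 ± 4.09 to 2.18 ± 0.396 CPM (log2 fold change -2.44, SE 0.24, adjusted p = 1.5e-05). Il1rn, encoding the interleukin-1 receptor antagonist and not on this list, also fell, from 290 ± 4.4 to 45.6 ± 1.35 CPM (log2 fold change -2.67, SE 0.05). Il6 fell from 1.72 ± 0.889 to 0.289 ± 0.154 CPM (adjusted p = 0.00064), and Nos2, the inducible nitric oxide synthase gene, from 1.3 ± 0.509 to 0.0476 ± 0.0442 CPM (adjusted p = 5.2e-05), the latter with counts of 5, 4 and 0 in the BW723C86 libraries. The log2 fold change of Nos2 was -4.72, and -5.36 without BW723C86 replicate 1. Tnf, encoding tumour necrosis factor, was at 17.7 ± 0.703 and 16.2 ± 1.08 CPM and did not pass (log2 fold change -0.13, SE 0.08, adjusted p = 0.22). Il10 was too low to test, with counts of 5, 4 and 0 in DMSO and 0 in each BW723C86 library. Among NF-kB pathway feedback genes, 10 of 20 fell, 1 rose and 9 did not pass (11 lower and 1 higher adjusted over the list alone, adjusted p = 0.0044, and 0.34 with an estimated correlation). Bcl3, an atypical inhibitor of NF-kB, and Birc3, an inhibitor of apoptosis, fell by 0.96 and 0.67 on the log2 scale. The mitochondrial superoxide dismutase gene Sod2 and the anti-apoptotic gene Bcl2a1a fell by 0.52 and 0.41.

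Markers of other myeloid cells moved with these genes. All 13 tested neutrophil markers fell, with 13 lower adjusted over the list alone (median log2 fold change -2.51, adjusted p = 3.1e-10, and 0.057 with an estimated correlation). S100a8 and S100a9, the calprotectin subunit genes, fell from 49.6 ± 2.16 to 4.7 ± 0.273 CPM and from 54.3 ± 0.961 to 3.55 ± 0.176 CPM. The lactoferrin gene Ltf fell from 24.9 ± 0.703 to 1.8 ± 0.151 CPM. The summed neutrophil markers were 2720 ± 42.7 CPM in DMSO and 764 ± 55.1 CPM with BW723C86, with no overlap between groups (exact permutation p = 0.1, the smallest that 3 against 3 allow). Most of that sum was Mmp8, the neutrophil collagenase gene, at 2420 CPM in DMSO. Of 14 monocyte markers, 11 fell, 2 rose and 1 did not pass, as also when adjusted over the list alone (median -1.36, adjusted p = 2.2e-05, and 0.084 with an estimated correlation). Their sum was 6910 ± 30.1 CPM in DMSO and 2210 ± 31.7 CPM with BW723C86 (exact permutation p = 0.1). Ly6c2, a surface antigen of inflammatory monocytes, fell from 300 ± 3.93 to 39.6 ± 1.13 CPM and the versican gene Vcan from 141 ± 1.81 to 13.5 ± 0.748 CPM. Lymphocyte and mast cell markers fell for 7 of 11 genes, both over all genes and adjusted over the list alone (median -1.7, adjusted p = 0.002, and 0.12 with an estimated correlation). Their sum was 112 ± 2.81 and 61.8 ± 2.96 CPM (exact permutation p = 0.1). The mast cell carboxypeptidase gene Cpa3, which gave most of the fall in that sum, fell from 51.6 ± 2.62 to 11.7 ± 1.45 CPM. The mast cell tryptase gene Tpsb2 fell from 1.99 ± 0.273 to 0.208 ± 0.122 CPM. Cd4 fell from 4.49 ± 0.582 to 1.38 ± 0.0421 CPM and the B cell receptor gene Cd79a from 1.1 ± 0.164 to 0.0867 ± 0.0753 CPM. Kit, the stem cell factor receptor gene of the same list, was at 46.4 ± 2.02 and 44.9 ± 1.47 CPM and did not pass (adjusted p = 0.54).

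Of 14 genes of MHC class II antigen presentation, 8 rose, 4 fell (Cd80, Cd86, H2-Oa and H2-DMb2, listed after their values were seen) and 2 did not pass, with the same counts adjusted over the list alone (median 0.76, adjusted p = 0.0092, and 0.33 with an estimated correlation). Cd74, the invariant chain, rose from 2470 ± 1.22 to 9420 ± 719 CPM. Ciita, the transactivator of MHC class II genes, rose from 44.1 ± 2.12 to 157 ± 3.2 CPM and the peptide-loading gene H2-DMb1 from 133 ± 3.97 to 518 ± 40.1 CPM. Cd86, encoding a T cell co-stimulator, fell from 60.2 ± 0.818 to 30.4 ± 2.29 CPM (adjusted p = 4.9e-08). Dendritic cell markers moved with this group: 7 of 14 rose, 2 fell and 5 did not pass (9 higher and 2 lower adjusted over the list alone, median 1.1, adjusted p = 0.0012, and 0.22 with an estimated correlation). Their sum, made up mainly of H2-Aa and Itgax, went from 1200 ± 2.7 to 5000 ± 181 CPM (exact permutation p = 0.1). H2-Aa is also on the MHC class II list. That list includes co-stimulator genes and a cathepsin gene shared with the lysosome list. Cd209a, a C-type lectin gene of dendritic cells, rose from 7.77 ± 0.208 to 30.8 ± 0.931 CPM. Fscn1, encoding the actin-bundling protein fascin, rose from 7.27 ± 0.876 to 19.8 ± 2.46 CPM. Macrophage identity markers went both ways, 6 higher, 8 lower and 4 not past, as also when adjusted over the list alone (adjusted p = 0.5), and their sum was 40700 ± 483 and 36400 ± 675 CPM (exact permutation p = 0.1). Most of that sum and of its fall was Lyz2, a lysozyme gene, at 32900 ± 432 CPM in DMSO and 29400 ± 620 CPM with BW723C86.

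Lysosomal genes were mostly higher. Of 35 lysosome and autophagy genes, 30 rose, none fell and 5 did not pass, and 32 were higher and 1 lower adjusted over the list alone (median log2 fold change 0.47, adjusted p = 1.2e-11, and 0.11 with an estimated correlation). The cathepsin genes Ctsb and Ctsk, of lysosomal proteases, rose from 2880 ± 13.6 to 9620 ± 223 CPM and from 27.6 ± 0.794 to 132 ± 3.15 CPM. Lipa, the lysosomal acid lipase gene, rose from 335 ± 1.4 to 821 ± 25.8 CPM and Gpnmb, encoding a lysosomal transmembrane glycoprotein, from 6360 ± 78.4 to 14000 ± 607 CPM. Phagocytosis and efferocytosis, the uptake of apoptotic cells, gave 20 genes higher, 6 lower and 8 not past of 34, with 20 and 6 adjusted over the list alone (median 0.29, adjusted p = 0.0023, and 0.11 with an estimated correlation). Mfge8, encoding a bridge between phosphatidylserine and integrins, rose from 588 ± 5.04 to 2830 ± 260 CPM. The TAM receptor kinase genes Tyro3 and Mertk rose from 3.96 ± 0.414 to 25.1 ± 1.81 CPM and from 39.2 ± 0.944 to 67.6 ± 2.8 CPM. Stab1, a scavenger receptor gene of the same list, fell from 25.8 ± 0.564 to 2.68 ± 0.105 CPM.

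Genes known from disease-associated microglia and lipid-associated macrophages were higher in 16 of 24 cases, lower in 5 and not past in 3 (17 higher and 5 lower adjusted over the list alone, median 0.43, adjusted p = 0.00026, and 0.17 with an estimated correlation). Many of the 16 also stand on lists given above, such as Gpnmb and Ctsb (lysosome), Trem2 (phagocytosis) and Itgax (dendritic cells). Their rise is therefore not separate evidence. The lipoprotein lipase gene Lpl rose from 503 ± 8.87 to 1410 ± 59 CPM and Trem2, a lipid-sensing receptor gene, from 295 ± 13.5 to 461 ± 48.5 CPM. The apolipoprotein gene Apoe fell from 504 ± 5.6 to 179 ± 9.71 CPM. Spp1, encoding osteopontin, was at 1570 ± 22.8 and 1700 ± 119 CPM and did not pass (adjusted p = 0.091), although it did with GC and length trends removed (4.5e-06). The growth factor gene Igf1 rose from 28.5 ± 1.02 to 97.3 ± 5.25 CPM. Of 10 osteoclast markers, 7 rose, 2 fell and 1 did not pass, as also adjusted over the list alone (median 0.54, adjusted p = 0.0084, and 0.16 with an estimated correlation). Some of the 7, such as Ctsk, also stand on the lysosome list. Acp5, encoding tartrate-resistant acid phosphatase, rose from 51.1 ± 1.7 to 106 ± 11.5 CPM, and Tnfrsf11a, encoding the receptor RANK, from 12.1 ± 0.556 to 19 ± 0.319 CPM. The summed osteoclast markers were 655 ± 0.937 and 1060 ± 43.3 CPM (exact permutation p = 0.1). Opposite changes were seen in markers of alternative activation: Arg1, the arginase-1 gene, fell by 1.6 on the log2 scale, and Mrc1, the mannose receptor gene, rose by 0.32, a call that was lost against a fold change of 1.2 (adjusted p = 0.13).

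Cholesterol synthesis genes rose in 17 of 24 cases, with none lower and 7 not past (18 higher adjusted over the list alone, median 0.43, adjusted p = 6.3e-07, and 0.057 with an estimated correlation). The sterol reductase gene Dhcr7 rose from 36 ± 1.74 to 68.1 ± 6.23 CPM and Fdps, encoding farnesyl diphosphate synthase, from 52.9 ± 2.42 to 86.5 ± 5.02 CPM. Among targets of NRF2, the regulator of antioxidant defence, 21 of 26 rose, 3 fell and 2 did not pass (22 higher and 4 lower adjusted over the list alone, median 0.43, adjusted p = 2.2e-05, and 0.11 with an estimated correlation). Srxn1, encoding sulfiredoxin, rose from 61.8 ± 1.01 to 200 ± 3.33 CPM and Gclm, a subunit of the enzyme that limits glutathione synthesis, from 92.4 ± 5.54 to 215 ± 12.2 CPM. The peroxiredoxin gene Prdx1 rose from 924 ± 10.6 to 1470 ± 14.1 CPM and the haem oxygenase gene Hmox1 from 173 ± 5.18 to 231 ± 3.81 CPM. The glutathione reductase gene Gsr fell from 123 ± 2.78 to 72.2 ± 2.79 CPM. The list of aryl hydrocarbon receptor targets also holds the receptor gene Ahr. Of its 8 genes, 6 fell and 2 rose, as also adjusted over the list alone (median -0.9, adjusted p = 0.0068, and 0.28 with an estimated correlation). Serpinb2, with its log2 fold change of -7.51, was among the 6, and the mean of the list was -1.38. Cyp1b1, Ahrr and Tiparp, all induced by that receptor, fell by 1.33, 1.06 and 0.74 on the log2 scale. Ahr itself, counted among the 6, fell by 1.17, whereas the quinone reductase gene Nqo1, shared with the NRF2 list, rose by 1.06.

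All 13 mitochondrially encoded transcripts fell, also adjusted over the list alone (median log2 fold change -0.69, adjusted p = 4e-07, and 0.33 with an estimated correlation). Their sum was 42800 ± 208 CPM in DMSO and 31100 ± 2200 CPM with BW723C86 (exact permutation p = 0.1). As percentages these TMM-scaled sums were 4.28% and 3.11%, which are not raw shares of the counts. The complex I subunit genes mt-Nd4 and mt-Nd1 fell from 2720 ± 50.5 to 1310 ± 82.3 CPM and from 2830 ± 18.8 to 1420 ± 93.6 CPM. The transcripts mt-Nd4l and mt-Co2, of complexes I and IV, fell by 0.98 and 0.71 on the log2 scale. Of 33 nuclear genes of oxidative phosphorylation, 17 rose, none fell and 16 did not pass (18 higher adjusted over the list alone, median 0.17, adjusted p = 0.0093, and 0.48 with an estimated correlation). The ATP synthase genes Atp5a1, Atp5c1 and Atp5o and the complex I gene Ndufs3 rose by 0.29 to 0.35 on the log2 scale, and none of the 4 passed against a fold change of 1.2 (adjusted p = 0.079 to 0.35). Cytosolic ribosomal protein genes fell in 27 of 38 cases, rose in 1 and did not pass in 10 (28 lower and 1 higher adjusted over the list alone, median -0.26, adjusted p = 4.5e-05, and 0.42 with an estimated correlation). Rpl30, Rpl23 and Rpl7, large-subunit proteins, fell by 0.58, 0.43 and 0.35 on the log2 scale. Their list summed to 33400 ± 497 and 28800 ± 2070 CPM (exact permutation p = 0.1).

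In the remaining lists past the threshold, members were split or the call depended on the setting. Interferon-stimulated genes gave 15 higher, 1 lower and 15 not past of 31 (15 higher and 2 lower adjusted over the list alone, median 0.39, adjusted p = 0.0071, and 0.16 with an estimated correlation). Oasl2, a relative of the oligoadenylate synthetases, rose from 6.83 ± 1.32 to 16.4 ± 0.577 CPM and Gbp2, a guanylate-binding protein gene, from 32.5 ± 0.772 to 46.4 ± 1.65 CPM. Oasl1 rose from 0.306 ± 0.0556 to 1.49 ± 0.268 CPM. Ifi205, an interferon-inducible gene of the same list, fell from 4.45 ± 0.335 to 1.6 ± 0.399 CPM. The list did not pass among genes of at least 5 CPM (adjusted p = 0.18). Immediate early genes gave 11 higher, 5 lower and 9 not past of 25 (11 higher and 6 lower adjusted over the list alone, median 0.13, adjusted p = 0.018, and 0.16 with an estimated correlation). Egr1 and Fos, transcription factor genes induced within minutes of receptor stimulation, rose from 10.7 ± 0.288 to 52.8 ± 3.45 CPM and from 16.4 ± 1.36 to 38.7 ± 2.1 CPM. The phosphatase gene Dusp1 and the transcription factor gene Atf3 rose by 1.49 and 1.31 on the log2 scale. Dusp6, a phosphatase gene that limits ERK signalling, fell from 147 ± 3.14 to 55.3 ± 3.61 CPM. That list missed the threshold without DMSO replicate 3 (adjusted p = 0.055), without BW723C86 replicate 1 (0.052) or 3 (0.053), among genes of at least 5 CPM (0.051) and with GC and length trends removed (0.12). Of 18 TGF-beta targets, 8 fell, 2 rose and 8 did not pass, as also adjusted over the list alone (median -0.17, adjusted p = 0.023, and 0.17 with an estimated correlation). Thbs1, with its log2 fold change of -5.18, was among those that fell, and the mean of the list was -0.86. The list also holds ligand and receptor genes of the pathway. Id1, an inhibitor of helix-loop-helix factors, fell from 63.7 ± 4.94 to 22.9 ± 2.74 CPM and Pmepa1, a feedback inhibitor of the pathway, from 27.9 ± 1.4 to 16.6 ± 0.395 CPM. The type I receptor gene Tgfbr1 rose from 152 ± 6.13 to 196 ± 7.83 CPM. This call was lost among genes of at least 5 CPM (adjusted p = 0.051) and with counts divided by 4 (0.066). The proliferation marker gene Mki67 fell from 92.6 ± 4.54 to 59.3 ± 1.74 CPM, while its list gave 14 genes higher, 6 lower and 18 not past and did not pass as a set (adjusted p = 0.25).

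Neuronal markers were examined because HT22 cells shared the wells. Of 9 tested, 5 rose, none fell and 4 did not pass, as also adjusted over the list alone (median 0.79, adjusted p = 0.019, and 0.36 with an estimated correlation), and the list missed the threshold without DMSO replicate 1 (0.089) or BW723C86 replicate 1 (0.077). Their sum was low, at 25.1 ± 1.47 and 52.3 ± 3.64 CPM (exact permutation p = 0.1). The markers do not tell RNA of HT22 cells from expression in the macrophages, so a carry-over of HT22 RNA stays open. The synapsin gene Syn1 rose from 7.59 ± 0.648 to 19 ± 0.717 CPM and the tubulin gene Tubb2b from 5.8 ± 0.059 to 13 ± 0.607 CPM. The ubiquitin hydrolase gene Uchl1 and the enolase gene Eno2, also on the glycolysis list, rose by 0.79 and 1.2 on the log2 scale.

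**Figure D2:**
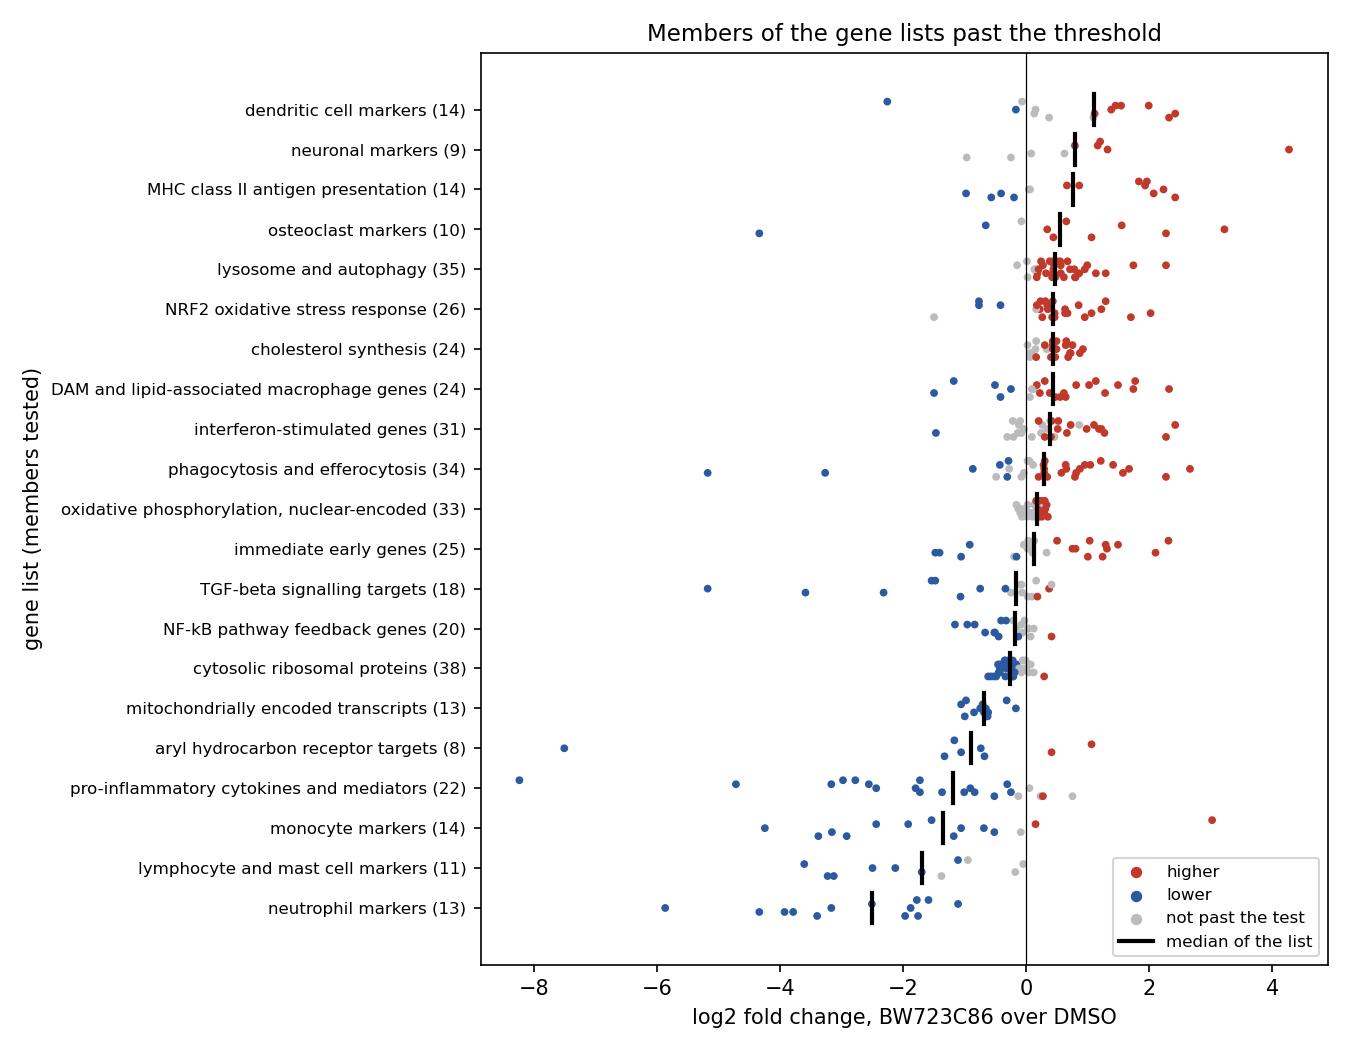
Log2 fold change (horizontal axis, BW723C86 over DMSO) of each tested member of the 21 lists past the threshold, with red points higher, blue points lower and grey points not past the test, and a black bar at the median of the list. Medians run from -2.51 for neutrophil markers to 1.1 for dendritic cell markers.

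**Figure D3:**
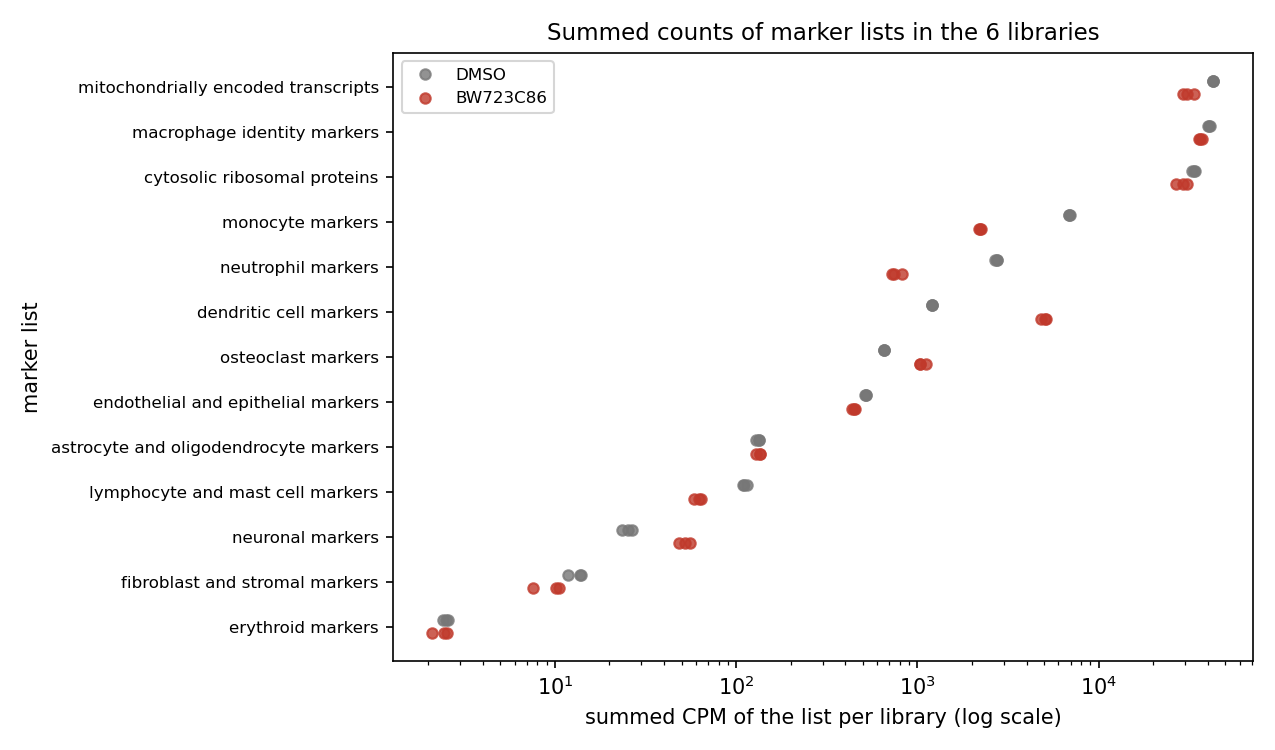
Summed CPM (horizontal log axis) of 13 marker and RNA quality lists in each DMSO (grey) and BW723C86 (red) library. Monocyte and neutrophil markers lie lower and dendritic cell markers higher in all 3 BW723C86 libraries than in any DMSO library, while erythroid and astrocyte and oligodendrocyte markers overlap.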

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

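Counts divided by 4, removal of GC and length trends, omission of mitochondrially encoded genes and gene families were alternatives chosen after seeing the data. The cause was not tested for any value below that moved or reversed, except where the setting itself tests fewer genes or asks for a larger fold. Over the other scalings, tools and filters, 5675 to 6835 genes changed, and leaving out a library in turn gave 5387 to 7153 (2715 to 3440 higher, 2623 to 3713 lower, 630 to 692 and 582 to 704 by at least 2-fold). Without BW723C86 replicate 2, 7153 genes changed. The direction was opposite for 15 genes called in both fits with GC and length trends removed and for none under the other settings, and 80.4 to 99.6% of the calls were shared, except against a fold change of 1.2. That stricter test left 3208 genes (1609 higher, 1599 lower), 49.1% of the calls. Requiring 5 CPM in 3 libraries tested 10224 genes and left 289 higher and 294 lower by at least 2-fold. DESeq2 was run on 24522 genes without the low-count filter and gave no adjusted p for 6144 of them. Il10 had too few counts to pass the expression filter and was not tested.

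The 12 lists higher and 9 lower became 0 and 0 with an estimated correlation and 19 and 21 with directional fry, and stayed at 10 to 12 and 9 with a library left out. Directions turned for 6 lists that did not pass. Alternative activation markers were lower with GC and length trends removed (adjusted p = 0.83) and in fry (0.00066), homeostatic microglia markers lower among genes of at least 5 CPM (0.82) and in fry (0.13), and complement higher among genes of at least 5 CPM (0.8). Integrated stress response targets were higher among genes of at least 5 CPM (0.93) and without BW723C86 replicate 2 (0.85, with 0.4 to 0.85 over the libraries left out in turn). Endothelial and epithelial markers were lower in fry (0.97), and astrocyte and oligodendrocyte markers higher in fry (0.0039) and with counts divided by 4 (0.94). Under camera, the adjusted p of these 6 lists ran from 0.2 to 0.95 over the alternatives. Of 114 named genes tested, Htr2a alone changed sign, to a log2 fold change of -0.03 without BW723C86 replicate 3 (-0.03 to 0.31 over the libraries left out in turn, 0.11 to 0.35 otherwise), and Rps24 joined Mrc1 and the 4 oxidative phosphorylation genes in losing its call against a fold change of 1.2 (adjusted p = 0.067).

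Taking the median of the members in place of the log2 ratio of summed CPM moved mitochondrially encoded transcripts from -0.46 to -0.69, osteoclast markers from 0.7 to 0.54, macrophage markers from -0.16 to -0.07, neuronal markers from 1.06 to 0.79, dendritic cell markers from 2.06 to 1.1, neutrophil markers from -1.83 to -2.51, lymphocyte and mast cell markers from -0.85 to -1.7 and monocyte markers from -1.64 to -1.36. It reversed endothelial and epithelial markers, from -0.22 to 0.53, and astrocyte and oligodendrocyte markers, from 0.02 to -0.26. With the replicate number as a block, 6179 genes changed (3123 higher, 3056 lower) and 13 lists were higher and 9 lower, and apart from the serotonin list it changed no call of a list or named gene. No pairing by number was seen: same-numbered samples had correlations of -0.09, -0.2 and -0.08 across 6821 genes, and other pairs -0.08 to 0.19. These values cannot exclude a pairing, because trends of single libraries with GC content can hide what paired samples share.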

Other observations

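The gene families, the genes picked out in the next 2 paragraphs, the tests with counts divided by 4 and with GC and length trends removed, and the tests of neutrophil content, of immature cells, of admixture and of GC content in a single library and in pairs of libraries were chosen after the data or the results were seen.

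Several lists did not pass as sets while members past the test went opposite ways. Levels are means of 3 libraries. In complement, 6 of 15 genes were higher and 8 lower (adjusted p = 0.59). The C1q chain genes C1qa, C1qb and C1qc, whose product opens the classical pathway, rose by 1.57, 1.67 and 1.41 on the log2 scale, while C3, the central component, fell from 813 to 259 CPM (log2 fold change -1.65, SE 0.04) and Itgam, a chain of the complement receptor CR3, from 2090 to 976 CPM. Among 18 chemokine genes 5 rose and 7 fell (adjusted p = 0.2): besides Ccl17, Cxcl16 rose from 146 to 358 CPM, and besides Cxcl3, Pf4, encoding platelet factor 4, fell from 150 to 14.8 CPM. Alternative activation markers were 10 higher and 10 lower of 23 (adjusted p = 0.89), with the lectin gene Mgl2 rising from 170 to 848 CPM and the chitinase-like gene Chil3 falling from 3200 to 1100 CPM. In the glycolysis and hypoxia list (6 higher, 14 lower of 33, adjusted p = 0.16, and 0.0078 with GC and length trends removed), Hif1a, encoding the oxygen-regulated transcription factor, fell from 268 to 94.3 CPM. Il1rn, which encodes the interleukin-1 receptor antagonist, fell from 290 to 45.6 CPM. Each gene named here passed the test, and had all 3 libraries of a group above all 3 of the other.

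The remaining lists that did not pass were p53 targets (3 higher, 11 lower, adjusted p = 0.086), LXR targets (9 and 5, 0.17, and 0.047 among genes of at least 5 CPM), fibroblast markers (1 and 2, 0.25), fatty acid handling (8 and 4, 0.31), phosphoinositide and calcium signalling (10 and 5, 0.5), endothelial and epithelial markers (4 and 2, 0.56), matrix remodelling (8 and 11, 0.56), ferroptosis and iron handling (7 and 10, 0.67), the unfolded protein response (8 and 6, 0.67), erythroid markers (0 and 1, 0.68), heat shock genes (3 and 5, 0.69), astrocyte and oligodendrocyte markers (2 and 3, 0.69), the integrated stress response (6 and 7, 0.69), homeostatic microglia markers (5 and 4, 0.78) and growth factors (5 and 5, 0.78). The homeostatic microglia list had a median log2 fold change of 0.28 and a mean of -0.29 (tested as higher), the integrated stress response 0.01 and -0.12 (lower), and phosphoinositide and calcium signalling 0 and -0.02 (higher). Of 211 families that share the start of their symbol, 6 passed camera with the preset correlation and 0 with an estimated correlation (adjusted p = 0.94 for each of the 6, and 5 families at an unadjusted p under 0.05). Histone genes were 13 higher and 0 lower of 25 (median 1.03, adjusted p = 0.00053). Hist1h1c, encoding a linker histone, rose from 76.7 to 171 CPM. Messages of replication-dependent histones mostly lack poly(A), so their level in poly(A)-selected libraries need not follow their total level. Kallikrein genes were 6 higher and 0 lower of 8 (adjusted p = 0.0096), solute carriers 99 and 33 of 221 (0.016), zinc finger genes named Zfp 26 and 104 of 347 (0.047), Rpl genes 1 and 26 of 48 (0.00053) and Rps genes 4 and 26 of 41 (0.021). Other scalings moved the median of all genes by 0.01 at most.

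For the number of changed genes, of the 10 splits of the 6 libraries into 3 and 3, 1 (the real split) gave as many as 6534 genes, and the highest other gave 2; for lists 1 split gave 21 and the highest other 10, and 10 splits are too few for a share under 0.05. The other splits mix the groups 2 to 1, so that a difference between the groups enters the spread within each side. A low number of gene calls is then fixed in advance, and the 2 genes are no measure of chance. These splits also keep part of any difference between the groups, and passed 3 to 10 lists. A GC content or transcript length bias as the whole cause is argued against, since 85% of the changed genes stayed past the threshold in the same direction with the trends removed, although the log2 fold change itself followed GC content with a Spearman rho of 0.27 across 6798 genes (-0.01 for length), so that a part stays open. Also argued against is the scale of the counts, since 6632 genes changed with counts divided by 4. An effect of the agonist stays open and was not separated from any other difference between the culture wells.

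Lower neutrophil and monocyte markers may reflect fewer such cells or lower expression within the macrophages. The neutrophil granule genes Ngp and Ltf fell from 72.5 to 18.6 and from 24.9 to 1.8 CPM, as a smaller share of neutrophils would give. Retnlg and Camp, also abundant in neutrophils, together reached at most 0.369% of S100a8 and S100a9 in any DMSO library (Retnlg 0.078 and Camp 0.173 CPM on average, against 49.6 and 54.3 CPM), which argues against a changed share of neutrophils as the whole cause but leaves a contribution open. Of the 13 neutrophil markers, 3 (Mmp8, Mmp9 and Lcn2) also stand on other lists used here. A smaller share of immature cells cannot be told apart from a change within each cell, because macrophage identity markers went both ways, with 42.9% of those past the test higher, and an effect of the agonist itself was not tested apart from the grouping.

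BW723C86 replicate 2 lay farthest from its group by the chi-square of counts, though not on the second principal component, and both tests of it had their deciding values replaced after a first result was seen, for admixture the difference between the medians of higher and lower genes. Admixture of DMSO cells or RNA is argued against for abundant genes lower with BW723C86: over the 35 genes with a mean of at least 20 CPM that were at least 4-fold lower in replicates 1 and 3 than in DMSO, the library lay a median fraction of 0.002 of the way toward DMSO, with an upper 95% bootstrap bound of 0.0074, although over 28 genes higher by the same limits the median was 0.052 (95% interval -0.015 to 0.13). A GC bias is a candidate explanation: across 6798 genes, which are not independent replicates, its deviation from the other replicates followed GC content with a Spearman rho of -0.69 (0.58 and 0.39 for replicates 1 and 3, -0.25 to 0.28 in DMSO) and length with 0.35, and by pairs rho was 0.66 for replicate 1 minus 2, -0.65 for 2 minus 3 and 0.27 for 1 minus 3 (-0.2 to 0.3 in DMSO). Removing the trend took away 44.4% of its mean squared deviation, which misses the bar of a majority set at first, and 72.1% of the excess over DMSO libraries, a bar set after the first result was seen. No biological explanation was tested for this library.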
